A study of Mus musculus with 11 samples.

How the data were processed

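RNA-seq libraries were analysed from mouse embryonic fibroblasts (MEFs), primary connective tissue cells grown from embryos of embryonic day 13.5 and collected at passage 2. The 11 libraries fell into 4 genotypes by their labels: 3 wild-type (WT), 3 Trex1-/-, 3 Trex1 D18N and 2 Trex1 p212fs. Per the labels' protocols, RNA was purified with an RNeasy kit and libraries were made with a SMARTer mRNA-seq kit. The deposited table held raw counts of reads per gene, which the authors had not normalized, as the whole numbers and the unequal library totals showed. Per the submitters' processing notes, fastp, HISAT2, featureCounts and the mouse build GRCm39 were used. Their versions, settings, roles, the annotation release, the strand setting and the treatment of overlapping genes were not given in the sources used here.

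Library totals ran from 16073955 to 21765536 counts. The table had 55578 lines, of which 1654 carried no gene name; these took between 0.0804% and 0.129% of a library's reads and stayed out of library sizes and tests. A further 1597 lines repeated a gene name already present. No sample column was left unused. Counting intervals and floors given for genes with few counts cover counting error only, because reads without molecular identifiers are not independent molecules. A floor of 3 counts over a group was used for genes at 0, and intervals had a confidence level of 95%.

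Genes were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the counts, after filterByExpr with a minimum count of 10 and TMM scaling, with robust estimation. One fit held all 11 libraries with genotype as the only term, so that the group of 2 libraries shared the estimate of the spread, and 6 comparisons were drawn from it. P-values were adjusted over the 16990 genes tested by the Benjamini-Hochberg method, and the threshold was an adjusted p of 0.05. The common biological coefficient of variation was 22.5%. Errors of log2 fold changes are approximate standard errors, taken as the absolute log2 fold change over the square root of the test's F statistic. They are least exact for genes with few counts in a group. Errors of counts scaled to the library total (CPM) are standard deviations between libraries. Nothing in the labels states that libraries of a genotype came from separate embryos or cultures, so the p-values measure the spread between these libraries. Xist had 941 CPM in Trex1-/- replicate 2 against 0.179 and 0 in replicates 1 and 3, and 1045 CPM in D18N replicate 1 against 0.0569 and 0 in replicates 2 and 3. Within these genotypes not all libraries came from the same embryo. Between libraries of the same sex pattern, as in WT and p212fs, the spread may be technical.

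There were 26 gene lists, covering interferon-stimulated genes, DNA and RNA sensing, inflammatory cytokines and chemokines, MHC class I antigen presentation, p53 targets, cell cycle, senescence, extracellular matrix, myofibroblast genes, Hox genes, positional factors, unfolded protein and integrated stress response, glycosylation, lysosome, cholesterol synthesis, hypoxia and glycolysis, imprinted genes, sex-linked genes and markers of macrophages, endothelium, epithelium, neurons and glia, skeletal muscle, cartilage and bone, adipocytes and erythroid cells. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Camera sets a list against the other genes, while fry asks whether the genes of a list moved, on balance, one way. Counts of list members past the threshold are to be read beside the counts over all genes given for each comparison. The lists, the tests and the rule for naming genes were set before the data were examined.

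By that rule the text names Trex1; in each comparison with WT the 8 higher and 8 lower genes with the largest fold change among those past the threshold, with a mean of at least 5 CPM in one group and no overlap between the libraries of both groups; in each comparison between mutants 5 and 5 such genes; for each list the 3 members with the smallest p among those past the threshold, or the 2 most abundant members where none passed; and Xist with the highest Y-linked gene. Predicted and unnamed genes were left out of the ranking. Not every gene that the rule picked is named in the text, while counts of genes named by rule cover all it picked. Other genes are marked as chosen after their values were seen. Some single-gene results of the cholesterol list are not reported here.

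Gene lengths, GC content, chromosomes and overlaps came from the GENCODE M21 annotation of GRCm38, which is not the build named by the submitters, so coordinates are given for GRCm38 only. Of 52327 distinct names in the table, 49940 matched it directly and 531 through synonyms, and 16797 of the genes tested (98.9%) had a length and GC content.

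The tests were tested on simulated counts of 16492 genes with 100 genes changed 2-fold and 100 changed 4-fold. For Trex1-/- against WT, edgeR recovered 61% of the 2-fold and 83% of the 4-fold changes; for D18N against WT 53% and 84%; for p212fs against WT 33% and 86%. It called 7 unchanged genes in each. DESeq2 called 25, 32 and 35 unchanged genes in the same 3 comparisons. Simulated genes varied independently of each other, with the same spread per gene in all groups. The shares recovered are therefore no measure of power where genes of a library moved together, as interferon-stimulated genes did in Trex1-/- replicate 2. A length trend of -0.1 put into 16544 simulated genes for p212fs against WT was estimated at -0.0964 without and -0.00263 with the length and GC offset described next.

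Alternatives were DESeq2 size factors, no filter on low counts, a filter of at least 1 CPM in 3 libraries, DESeq2 (1.42.0), limma-voom, fits of only the groups compared, the replicate number as a block, X and Y genes left out, embryo sex as a term, and each library left out in turn. An offset per library for gene length and GC content, and the sex term for gene lists, were added after seeing the data. With the offset, camera ran on log2 CPM less the trend, and in all other settings on the counts held by edgeR. A list call that ended or appeared with the offset is thus not shown to depend on length or GC content. Sex was read from Xist and Y-linked counts. Comparisons with WT share the WT libraries, so their correlations and overlaps were set beside those of 20 simulated data sets with unchanged groups.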

Results

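Gene expression was measured by RNA-seq in mouse embryonic fibroblasts of 4 genotypes at the Trex1 locus. TREX1 is an exonuclease that degrades DNA in the cytosol, where unremoved DNA can trigger type I interferon. D18N changes a residue of its active site and, in people, causes familial chilblain lupus, while p212fs is by its name a frameshift. There were 3 WT, 3 Trex1-/-, 3 Trex1 D18N and 2 Trex1 p212fs libraries. Total counts were 18091106, 16073955 and 18457274 in WT replicates 1, 2 and 3, and 21765536, 19561004 and 18127353 in Trex1-/-. They were 17646873, 18078706 and 17946122 in D18N, and 17868776 and 18515214 in p212fs. Spearman correlations between libraries of a genotype ran from 0.960, between Trex1-/- replicates 1 and 2, to 0.994, between the p212fs libraries. Every pair differed by more than sampling noise, with chi-square per degree of freedom from 7.94 (p212fs) to 129 (Trex1-/- replicates 1 and 2).

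**Figure D1:**
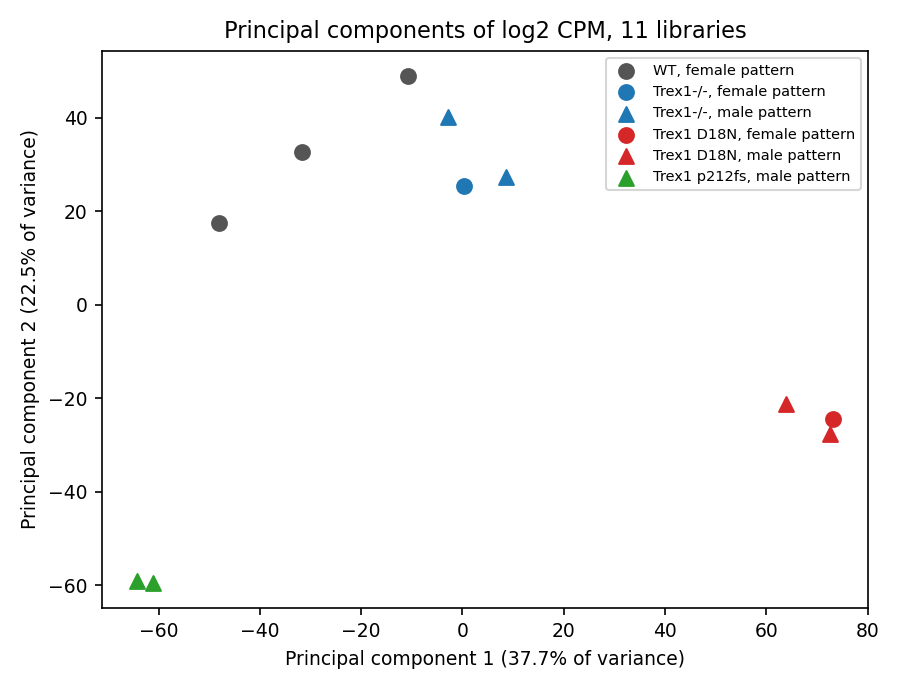
Principal components 1 (37.7% of the variance, x axis) and 2 (22.5%, y axis) of log2 CPM, 1 point per library, coloured by genotype, with circles for libraries of female and triangles for those of male pattern. The 3 D18N and the 2 p212fs libraries each lay apart from the rest, and WT replicate 2 lay near the Trex1-/- libraries.

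Trex1 had 0 counts in all 11 libraries, WT included, so its counts check no genotype label. In GRCm38 it lies on chromosome 9 from 109057933 to 109059734, on the minus strand, and 100% of its 1147 exonic bases fall inside exons of Atrip (109057933 to 109074124) on the same strand. Of 112 protein-coding genes covered in this way by same-strand exons of other genes, 91 (81.2%) had 0 counts in every library, as had 31 of 33 (93.9%) covered by opposite-strand exons alone. Among 15232 genes with no exonic base inside exons of another gene, on either strand, 3389 (22.2%) did. Atrip, a partner of the checkpoint kinase ATR, had between 16.9 and 23.6 CPM.

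Xist, the RNA expressed from the inactive X chromosome, and Ddx3y, the highest of the Y-linked genes, split the libraries by embryo sex. The 3 WT libraries had 425, 904 and 580 CPM of Xist and none of Ddx3y, a female pattern. In Trex1-/-, replicate 2 (Xist 941 CPM) was female in pattern, and replicates 1 and 3 (Ddx3y 93.1 and 80.5 CPM) male. In D18N, replicate 1 (Xist 1045 CPM) was female, and replicates 2 and 3 (Ddx3y 77.5 and 80.1 CPM) male. Both p212fs libraries were male in pattern (Ddx3y 52.2 and 60.3 CPM). Sex was therefore confounded with genotype, fully between p212fs and WT and in part in the other comparisons except D18N against Trex1-/-. A sex term could be estimated only within Trex1-/- and D18N, which held both patterns. Between p212fs and WT it was borrowed from those genotypes, so calls kept with it are not shown to be free of sex.

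Comparing Trex1-/- with WT asks what the loss of the exonuclease does to fibroblast expression. Interferon-stimulated genes lay higher in the 3 Trex1-/- than in the 3 WT libraries as a group, with a median log2 fold change of 2.18 over 55 genes (camera adjusted p = 8.8e-39; adjusted p = 0.595 with an estimated correlation), although no member passed the threshold alone. Their 2 most abundant members were Lgals3bp, a secreted glycoprotein, and Bst2, which tethers budding virions to the cell. Lgals3bp had 717 ± 510 CPM against 235 ± 91.7 (log2 fold change 1.61 ± 0.44, adjusted p = 0.131), and Bst2 had 561 ± 427 against 182 ± 101 (1.62 ± 0.52, adjusted p = 0.141). Genes of MHC class I antigen presentation lay higher too (median 1.65 over 18 genes; adjusted p = 0.595 with an estimated correlation), among them B2m, its light chain, at 1167 ± 484 CPM against 508 ± 171 (1.20 ± 0.28, adjusted p = 0.125). Markers of macrophages lay lower (median -1.42 over 20 genes; adjusted p = 0.281 with an estimated correlation), among them the lysozyme gene Lyz2, at 179 ± 53.8 CPM against 691 ± 56.4 (-1.95 ± 0.29, adjusted p = 0.0806).

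In these 3 lists no member passed over all genes tested; adjusted over the list alone, 53 interferon-stimulated and 15 MHC class I genes were higher and 15 macrophage markers lower. Camera gave adjusted p = 9.2e-14 for MHC class I and 3.2e-19 for macrophages at the preset correlation, and these calls, like that of the interferon list, were lost with an estimated one. DESeq2 called 48 interferon-stimulated and 12 MHC class I genes higher and 11 macrophage markers lower. Replicate 2 set much of the interferon difference. Its list mean was 7.76 log2 CPM, against 5.42 and 6.11 in the other Trex1-/- libraries and 5.06, 4.41 and 4.10 in WT. Without it the list median was 1.16, and that of MHC class I 0.85. With an offset for gene length and GC content, added after seeing the data, the medians were 2.05, 1.69 and -1.31 for the interferon, MHC class I and macrophage lists.

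**Figure D2:**
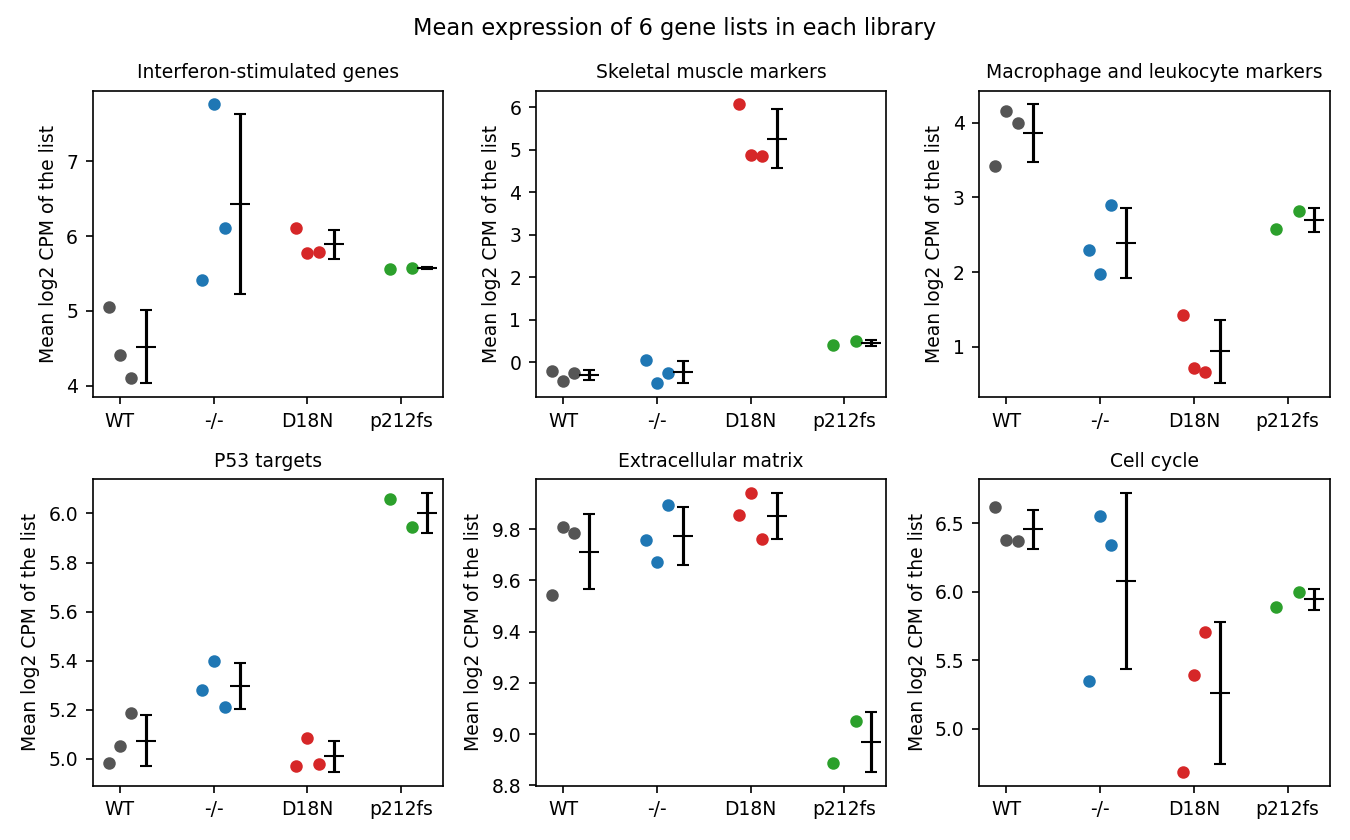
Mean log2 CPM (y axis) of 6 gene lists in each library, 1 panel per list and 1 point per library, grouped by genotype, with black dashes and bars for the group mean and SD. Muscle markers lay between 4.85 and 6.07 in D18N and between -0.49 and 0.50 in all other libraries, and the interferon-stimulated genes were highest in Trex1-/- replicate 2.

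Further lists passed by camera with no member past the threshold over all genes. Inflammatory cytokines and chemokines had a median of 0.99 over 31 genes (adjusted p = 0.0042; adjusted p = 0.957 with an estimated correlation), with Saa3, an acute-phase protein, at 1519 ± 1901 CPM against 617 ± 175. Its direction turned without Trex1-/- replicate 2, to a median of -0.17. Lower by camera were cell cycle genes (median -0.27 over 40 genes, adjusted p = 8.7e-04; adjusted p = 0.957 with an estimated correlation). Their call ended without Trex1-/- replicate 1. Myofibroblast genes were lower as well (-0.50 over 19 genes, adjusted p = 3.0e-04; adjusted p = 0.732 with an estimated correlation), with the smooth muscle actin Acta2 at 2034 ± 1076 CPM against 4613 ± 972. So was the stress response list (-0.19 over 28 genes, adjusted p = 0.0257; adjusted p = 0.792 with an estimated correlation). Targets of the tumour suppressor p53 (0.25 over 29 genes, adjusted p = 0.0165) and cartilage and bone markers (0.41 over 17 genes, adjusted p = 0.0049) were higher, both with adjusted p = 0.732 with an estimated correlation. The p53 call ended without WT replicate 2 or Trex1-/- replicate 2, and those of the cartilage and stress response lists without Trex1-/- replicate 1 and without WT replicate 2 or 1; that of the stress response list also ended with the length and GC offset. Adjusted over the list alone, these lists held 3 myofibroblast genes lower and 2 p53 targets and 2 cartilage or bone markers higher, and DESeq2 called 4, 4 and 2.

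Over all genes edgeR called 0 of 16990 between Trex1-/- and WT. An unadjusted p under 0.05 was reached by 3862 genes against 850 by chance, and the smallest adjusted p, 0.0617, was that of Tyrobp, a macrophage signalling adaptor. DESeq2 called 846 genes (543 higher, 303 lower) and limma-voom 1. Without WT replicate 2, edgeR called 2269 (1205 higher, 1064 lower); it called 105, 26 and 3 without Trex1-/- replicates 1, 2 and 3 and 2 without D18N replicate 1. With embryo sex as a term it called 380 and with no filter 261. The libraries of both groups did not overlap for 22.4% of genes, against 10% by chance.

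**Figure D3:**
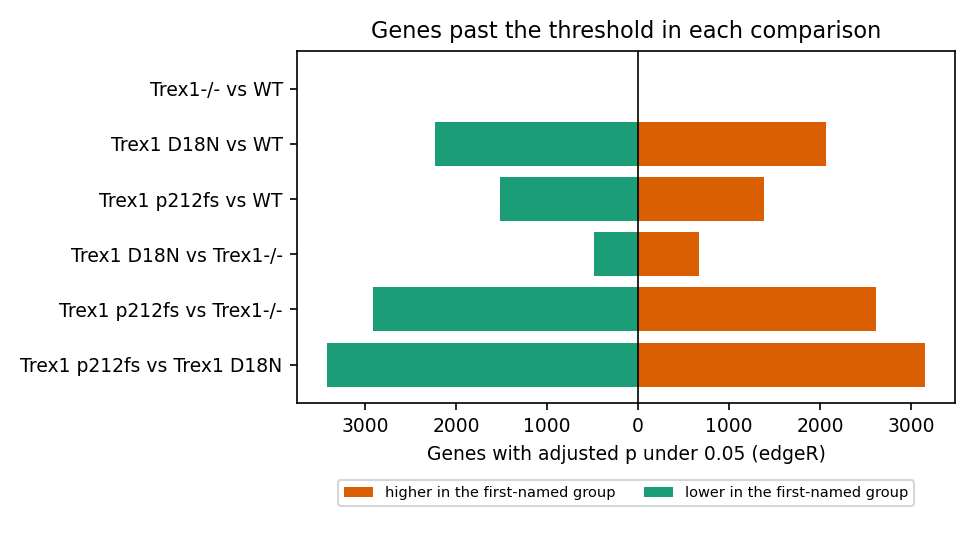
Number of genes (x axis) past an adjusted p of 0.05 in each comparison (y axis), with bars to the right of 0 for higher and to the left for lower genes. The counts run from 0 for Trex1-/- against WT to 3153 higher and 3418 lower genes for p212fs against D18N.

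Comparing D18N with WT asks what the active-site change does to the same cells. Skeletal muscle genes lay far higher in the 3 D18N than in the 3 WT libraries: all 25 tested rose, with a median log2 fold change of 6.57 (6.27 with 6 members of few counts at their bound). Among them were Neb, which encodes the giant thin-filament protein nebulin, at 69.3 ± 28.2 CPM against 1.03 ± 0.487 (6.07 ± 0.38), and the myosin light chain genes Mylpf (6.58 ± 0.44) and Myl1 (8.62 ± 0.58). Myog and Myod1, transcription factors of muscle differentiation, were 909-fold (95% interval 251 to 7513) and 653-fold (117 to 25812) higher. Macrophage markers fell, 19 of 20 (median -2.97), with Lyz2 at 59.4 ± 26.3 CPM against 691 ± 56.4 (-3.54 ± 0.31) and Tyrobp at -3.05 ± 0.25. Of 40 cell cycle genes 27 fell and none rose (median -1.11; adjusted p = 0.651 with an estimated correlation), among them the replication genes Mcm3 (-1.49 ± 0.25), Pcna (-1.21 ± 0.22) and Mcm2 (-1.15 ± 0.21).

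The muscle list kept its call with camera (adjusted p = 7.6e-66; adjusted p = 0.0441 with an estimated correlation), as did the macrophage list (1.9e-28; adjusted p = 0.0441 with an estimated correlation). The cell cycle list had adjusted p = 3.3e-16 at the preset correlation only. Adjusted over the list alone, 25 muscle genes rose, and 20 macrophage and 38 cell cycle genes fell. Of the 25 muscle genes 11 had a mean of at least 1 CPM in WT. Genes near 0 there entered the test only through libraries where they were high. Leaving out 1 library at a time gave 24 to 26 muscle genes higher, 17 to 20 macrophage markers lower, and 7 (without D18N replicate 2) to 38 cell cycle genes lower. With embryo sex as a term 8 cell cycle genes fell.

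Other genes were named by size of change. Higher in D18N were Mylk4, a muscle kinase gene with 0 counts in WT (at least 221-fold), and Art1, also at 0 in WT (at least 94.8-fold). Chrng and Chrnd, subunits of the muscle acetylcholine receptor, were 597-fold (165 to 4933) and 485-fold (86.6 to 19183) higher, and Lmod3, an actin nucleator of muscle, 439-fold (78.4 to 17390). Lower were Cx3cr1, a microglia and macrophage receptor (95.6-fold, 32.4 to 466), and Sprr2k of the clustered Sprr2 family, whose near-identical copies make its count uncertain (165-fold, 56.1 to 802). The scavenger receptor gene Marco (-5.76 ± 0.78), the complement receptor gene C5ar1 (-4.34 ± 0.34), Ms4a7 (-4.02 ± 0.44) and Spi1, a master transcription factor of myeloid cells (-4.01 ± 0.46), also fell. So did Gjb2, a connexin (-4.47 ± 0.59), and Ptgds, a prostaglandin synthase (-4.35 ± 0.45).

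Of 55 interferon-stimulated genes 53 had a log2 fold change above 0 in D18N against WT. Over all genes 12 passed, and adjusted over the list alone 11, all higher. The list median was 1.18 (camera adjusted p = 1.2e-08, and adjusted p = 0.651 with an estimated correlation). Ifi27l2a rose from 3.97 ± 2.55 to 42 ± 12.9 CPM (3.40 ± 0.58, adjusted p = 0.0047), the helicase gene Ddx60 by 2.39 ± 0.47 and Slfn5 by 1.61 ± 0.33. Of 18 MHC class I genes 5 rose (9 adjusted over the list alone, median 0.93; camera adjusted p = 0.0019; adjusted p = 0.651 with an estimated correlation): H2-T24 (1.82 ± 0.39), the transactivator Nlrc5 (2.21 ± 0.51), the heavy chain H2-D1 (1.68 ± 0.42), B2m and H2-K1. B2m and H2-K1 were named after their values were seen. The number of interferon-stimulated genes past the threshold ran from 4 (without WT replicate 3) to 44 (without Trex1-/- replicate 2), and that of MHC class I from 1 to 12 in the same fits. Trex1-/- replicate 2 is in neither group, but all libraries shared 1 estimate of the spread. The 12 and 5 calls are therefore no measure of how many of these genes differ. With embryo sex as a term 44 and 13 rose. That term was estimated only within Trex1-/- and D18N, and the only female-pattern Trex1-/- library was replicate 2, which set much of the interferon difference. The sex term therefore does not separate sex from that library. H2-D1 lost its call without WT replicate 2, WT replicate 3 or D18N replicate 1 and with no filter, and Nlrc5 without WT replicate 3 and with no filter.

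Genes of hypoxia and glycolysis rose in 11 of 28 cases and fell in none (11 higher adjusted over the list alone, median 0.32; camera adjusted p = 0.0032; adjusted p = 0.651 with an estimated correlation). Ddit4, an inhibitor of mTOR signalling, rose by 1.27 ± 0.15, Ero1a, an oxidase of the endoplasmic reticulum, by 1.09 ± 0.15 and Vegfa, an angiogenic factor, by 1.29 ± 0.22. Without WT replicate 3 only 3 members rose. Neuronal and glial markers fell in 8 of 23 cases and rose in 1, Dcx (median -1.24, or -0.84 at bounds; adjusted over the list alone, 10 lower and 1 higher). Fabp7 (-2.41 ± 0.30), Gap43 (-2.04 ± 0.32) and Olig1 (-3.55 ± 0.64) fell most clearly (camera adjusted p = 3.6e-04; adjusted p = 0.371 with an estimated correlation). In the stress response list 2 of 28 rose, Sel1l and Edem1 of protein quality control, and 7 fell, among them the serine and one-carbon metabolism genes Phgdh (-1.24 ± 0.18), Psat1 (-1.01 ± 0.20) and Shmt2 (-1.08 ± 0.24). Its camera adjusted p was 0.0163, with adjusted p = 0.651 with an estimated correlation, and the call ended without D18N replicate 1; adjusted over the list alone 2 rose and 9 fell. Dcx, Sel1l and Edem1 were named after their values were seen.

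Structural genes moved both ways in D18N. Of 19 myofibroblast genes Des (1.26 ± 0.22), the muscle intermediate filament, and Synpo2 (0.89 ± 0.27) rose, while Actg2 (-1.74 ± 0.48), Acta2, Myl9 and Tagln, genes of the contractile apparatus, fell (camera adjusted p = 0.0301; adjusted p = 0.651 with an estimated correlation). Adjusted over the list alone, 2 rose and 6 fell; camera lost the call without WT replicate 3 or D18N replicate 1 and with the length and GC offset. Of 44 extracellular matrix genes 9 rose, among them Col5a2 (1.10 ± 0.15) and Postn (1.23 ± 0.22), and 5 fell, Fmod (-1.69 ± 0.19), Eln, Timp2, Col4a1 and Col4a2; adjusted over the list alone 11 rose and 6 fell (camera adjusted p = 0.275). Of 29 p53 targets 5 rose, Ddit4, Pmaip1, Trp53cor1, Rrm2b and Polk, and 8 fell, also adjusted over the list alone (camera adjusted p = 0.420), with Phlda3 at -0.85 ± 0.15 and Aen at -0.79 ± 0.15. Among 36 Hox genes Hoxa9 (1.27 ± 0.17), Hoxc6 and Hoxa10 rose, and Hoxa4 and Hoxa2 fell; adjusted over the list alone 3 rose and 1 fell. Of 17 cartilage and bone markers Alpl (-1.89 ± 0.37), Col2a1 (-3.73 ± 0.70) and Col9a1 (-1.88 ± 0.50) fell, also adjusted over the list alone. Acta2, Myl9, Tagln, the matrix genes other than Fmod, Col5a2 and Postn, the p53 targets that rose other than Ddit4, Hoxa10 and Hoxa2 were named after their values were seen.

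In all, edgeR called 4303 genes between D18N and WT, 2065 higher and 2238 lower, of which 1013 and 756 changed at least 2-fold; 44.9% of genes did not overlap, against 10% by chance. The count was 1662 without D18N replicate 2, 2809 without D18N replicate 1, 2097 without WT replicate 3, 2249 without WT replicate 1 and 2379 with embryo sex as a term; an offset for gene length and GC content gave 1658 higher and 2928 lower. Of the 85 genes named by rule that passed here, 66 kept their call whichever library was left out and 75 with the sex term.

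Comparing p212fs with WT asks the same of the frameshift. Targets of p53 rose in the 2 p212fs libraries against the 3 WT: 17 of 29 were higher and 1, Sesn2, lower, with a median log2 fold change of 0.81. Pmaip1, a pro-apoptotic BCL2 family gene, rose from 6.97 ± 1.69 to 65.6 ± 9.28 CPM (3.23 ± 0.23, adjusted p = 5.1e-05), and Perp, a p53 effector in desmosomes, from 2.18 ± 0.39 to 34.5 ± 11.5 CPM (3.98 ± 0.34). Psrc1 rose by 1.67 ± 0.14, and Cdkn1a, the cell cycle inhibitor p21, from 182 ± 8.56 to 550 ± 48.9 CPM (1.60 ± 0.26). Extracellular matrix genes fell, 19 of 44, with 1 higher, the collagenase gene Mmp2 (median -0.57; camera adjusted p = 3.9e-10; adjusted p = 0.0693 with an estimated correlation). Col6a3 fell from 1644 ± 191 to 197 ± 40 CPM (-3.06 ± 0.22), Col15a1 from 57.6 ± 2.88 to 3.35 ± 0.0339 (-4.10 ± 0.29), and Col6a2 by 2.15 ± 0.22 on the log2 scale.

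Lysosomal genes rose, 20 of 36 and none lower (median 0.59; camera adjusted p = 3.5e-11; adjusted p = 0.313 with an estimated correlation), led by the proteases Ctsl, from 422 ± 57.3 to 921 ± 35.2 CPM (1.13 ± 0.16), Ctsa (1.02 ± 0.15) and Tpp1 (0.91 ± 0.14). For p53 targets camera gave adjusted p = 2.8e-15, and adjusted p = 0.0295 with an estimated correlation. Adjusted over the list alone, 18 p53 targets rose and 1 fell, 22 matrix genes fell and 2 rose, and 25 lysosomal genes rose and 1 fell. Without p212fs replicate 1 the counts were 9 p53 targets higher, 8 matrix genes lower and 8 lysosomal genes higher; with the sex term they were 14, 14 and 13. Sesn2 and Mmp2 were named after their values were seen.

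Long genes lay lower in p212fs than in WT, and short genes higher. The Spearman correlation across genes between log2 fold change and gene length was -0.185, with a median of 0.13 in the bin of shortest and -0.23 in the bin of longest genes; genes are not independent replicates. It was 0.339 between Trex1-/- and WT, 0.173 between D18N and WT, -0.0721 between D18N and Trex1-/-, -0.353 between p212fs and Trex1-/- and -0.280 between p212fs and D18N. With an offset for length and GC content, added after seeing the data, 1554 genes were higher and 1235 lower, and the medians were 0.78 for p53 targets, -0.50 for the matrix and 0.67 for the lysosome.

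Among single genes in p212fs, Ccl5, an interferon-induced chemokine, rose from 2.45 ± 1.44 to 282 ± 42.1 CPM (6.85 ± 1.60, adjusted p = 0.0212). Others higher were Sncg, gamma-synuclein (5.48 ± 0.25, adjusted p = 1.6e-06), Agt, angiotensinogen (4.52 ± 0.51), and Col2a1, the main cartilage collagen, from 25.9 ± 15.5 to 483 ± 117 CPM (4.22 ± 0.67). Cox6b2 (3.79 ± 0.42), the mast cell protease gene Mcpt8 (3.61 ± 0.86) and Sprr2b (5.11 ± 0.84), uncertain because of its near-identical copies, rose as well. Of those lower Gfap, the astrocyte filament, fell from 62.2 ± 24.3 to 2.2 ± 0.563 CPM (-4.81 ± 0.79), and the water channel gene Aqp4 (-4.79 ± 0.86), Olig1 (-4.53 ± 0.83) and Ncan (-4.44 ± 0.88) fell too. Adgrd1 (-4.71 ± 0.52), Gjb2 (-4.60 ± 0.70), the ion channel gene P2rx3 (-4.54 ± 0.41) and Cx3cr1 (-4.46 ± 1.23) completed the set. Without p212fs replicate 1 or 2 the calls of Ccl5, Gfap, Aqp4, Ncan, Cx3cr1 and Mcpt8 were lost, and without replicate 2 that of Olig1. Ccl5, Cx3cr1 and Mcpt8 also lost theirs without WT replicate 2 or 3, and Col2a1 with the sex term.

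In the stress response list 12 of 28 genes fell and 6 rose (median -0.29; camera adjusted p = 0.0085; adjusted p = 0.598 with an estimated correlation). Lower were Trib3, a pseudokinase gene, at -2.62 ± 0.27, Slc7a11, a cystine transporter, at -1.89 ± 0.24 and Asns, asparagine synthetase, at -1.78 ± 0.23. Those that rose were Calr, Pdia4, Dnajb9, Pdia6, Creld2 and Hsp90b1, which encode chaperones and folding factors of the endoplasmic reticulum and were named after their values were seen. Adjusted over the list alone 13 fell and 7 rose, and without p212fs replicate 1 the counts were 4 and 0. Among 36 Hox genes 8 rose and 11 fell (11 and 11 adjusted over the list alone), with Hoxd8 at -1.60 ± 0.15, Hoxc10 at -2.49 ± 0.32 and Hoxc11 lower 62.4-fold (17.0 to 519). Their median of 0.07 and mean of -0.66 differed in sign (camera adjusted p = 0.649), and without p212fs replicate 1 there were 3 in each direction. Of 23 neuronal and glial markers 7 fell, also adjusted over the list alone, with Sox2 at -3.04 ± 0.46 and Sox10 at -2.70 ± 0.45 (median -0.31, camera adjusted p = 0.0121; adjusted p = 0.598 with an estimated correlation). Without p212fs replicate 2 only 1 of them fell.

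Interferon-stimulated genes passed the threshold in p212fs in 3 of 55 cases, Ccl5, Ifit1 and Ddx60, and in 0 adjusted over the list alone (median 0.87; camera adjusted p = 6.4e-05; adjusted p = 0.867 with an estimated correlation). Of all 16990 genes tested 1382 were higher, a larger share than 3 of 55, while 46 of 55 had a log2 fold change above 0. Ifit1, an antiviral RNA-binding protein, rose from 57.3 ± 22.1 to 345 ± 9.83 CPM (2.59 ± 0.62, adjusted p = 0.0210) and Ddx60 by 1.83 ± 0.51. Their calls and that of B2m (0.99 ± 0.31) were lost without p212fs replicate 1 or 2 or WT replicate 2 or 3. The call of Ddx60 was lost without WT replicate 1 too, and that of B2m without Trex1-/- replicate 3 or any D18N library. In the interferon list 21 members rose with the sex term and 24 without Trex1-/- replicate 2. All libraries shared 1 estimate of the spread, so 3 of 55 is no measure of how many members differ. Trex1-/- replicate 2 entered that estimate although it is in neither group. The sex term drew in part on that library, the only female-pattern one of Trex1-/-. MHC class I genes had B2m higher and H2-T24 lower (-1.75 ± 0.51) of 18, and inflammatory genes the chemokine Ccl8 higher (3.41 ± 1.02) and Il33 lower (-1.80 ± 0.53) of 31. Their medians were 0.65 (camera adjusted p = 0.0446) and 0.89 (0.0206), both with adjusted p = 0.867 with an estimated correlation, and neither had a call adjusted over the list alone. The MHC class I call of camera ended with the length and GC offset.

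Macrophage markers fell in 4 of 20 cases in p212fs (9 adjusted over the list alone), with Csf1r, the receptor of macrophage colony-stimulating factor, at -1.82 ± 0.38, besides Cx3cr1, C1qb (-1.78 ± 0.52) and C1qc, the last named after its value was seen. Camera gave adjusted p = 1.8e-04, and adjusted p = 0.598 with an estimated correlation; 0 fell without p212fs replicate 1. Of 17 cartilage and bone markers 7 rose, with Col9a1 at 2.32 ± 0.46, and Runx2 fell (-0.72 ± 0.15). Adjusted over the list alone 8 rose and 2 fell (median 0.63). This list had a camera adjusted p of 0.0401, and adjusted p = 0.782 with an estimated correlation; with the sex term 0 rose and 2 fell, and camera lost the call with the length and GC offset. Cell cycle genes had 1 higher, Ccne1 (1.05 ± 0.29), and 1 lower, the proliferation marker Mki67 (-1.41 ± 0.35), of 40, and 0 adjusted over the list alone (median -0.59, adjusted p = 0.0035; adjusted p = 0.867 with an estimated correlation). Of 25 muscle genes Myog, 24.3-fold (6.23 to 208), and Acta1 (2.45 ± 0.55) rose, also adjusted over the list alone (median 1.19, or 0.82 at bounds; camera adjusted p = 0.0085; adjusted p = 0.867 with an estimated correlation). Of 19 myofibroblast genes none passed, with Acta2 at -0.15 ± 0.46.

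In all, 2902 genes passed between p212fs and WT, 1382 higher and 1520 lower, with 626 and 800 changed at least 2-fold; 53.3% of genes did not overlap, against 20% by chance. The count was 494 and 512 without p212fs replicates 1 and 2, where the lone library was assumed to vary like the other groups, 1522 and 1697 without WT replicates 3 and 2, and 1331 with the sex term. Of 73 genes named by rule that passed, 28 kept their call whichever library was left out and 49 with the sex term.

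Changes against WT were compared between mutants. Across 16990 genes the log2 fold changes of Trex1-/- and D18N correlated with r = 0.532 against 0.501 for simulated unchanged groups, with a covariance of 0.360 against 0.0663, a difference of 0.294. For Trex1-/- and p212fs r was 0.232 against 0.450 and the covariance 0.153 against 0.0668. For D18N and p212fs r was 0.209 against 0.445 and the covariance 0.222 against 0.0666. The simulated groups held no changes, while real changes widen the fold changes and can lower r. An r under the simulated one is therefore no sign of less sharing. Simulated genes were drawn independently of each other, so these data sets may understate how far chance moves both measures. D18N and p212fs shared 300 higher and 294 lower genes, where independent lists would share 168 and 200.2, and 278 genes changed in opposite directions. The 594 genes shared in direction became 131 and 111 without p212fs replicates 1 and 2, 242 without WT replicate 3 and 303 without D18N replicate 2. Simulated unchanged groups gave an overlap of 0, which is no measure of chance sharing. The 3 WT libraries could not be split into parts of at least 2, so part of the excess may come from the shared controls.

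The mutants were also compared with each other directly, which asks whether the alleles differ. D18N was set apart from Trex1-/- by the same muscle list: 24 of 25 genes rose (25 adjusted over the list alone), with a median of 6.21 (6.05 at bounds), Neb at 5.88 ± 0.37, Mylpf at 6.79 ± 0.44 and Myl1 at 8.38 ± 0.57. Camera gave adjusted p = 1.7e-110, and adjusted p = 0.00967 with an estimated correlation. Macrophage markers fell in 11 of 20 cases (18 adjusted over the list alone, median -1.51), with Adgre1, the F4/80 antigen, at -2.56 ± 0.44, Spi1 at -2.42 ± 0.45 and Lyz2 at -1.59 ± 0.29 (camera adjusted p = 1.8e-13; adjusted p = 0.265 with an estimated correlation). Without D18N replicate 2 there were 2. Cartilage and bone markers fell in 4 of 17 cases (7 adjusted over the list alone), Col9a1 (-3.57 ± 0.49), Col2a1 (-5.01 ± 0.72), Alpl (-2.26 ± 0.37) and Hapln1, the last named after its value was seen. For this list camera gave adjusted p = 2.4e-06, and adjusted p = 0.282 with an estimated correlation.

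Interferon-stimulated genes did not pass one by one between D18N and Trex1-/- (0 of 55, and 0 adjusted over the list alone; DESeq2 called 2 lower). Their median was -0.84, with Bst2 at -0.97 ± 0.51, and camera gave adjusted p = 1.1e-04 (adjusted p = 0.786 with an estimated correlation). Without Trex1-/- replicate 2 the direction turned, to a median of 0.02. Cell cycle genes fell in 7 of 40 cases (22 adjusted over the list alone, median -0.88; camera adjusted p = 2.2e-13; adjusted p = 0.456 with an estimated correlation), and in 0 without Trex1-/- replicate 3. Neuronal and glial markers fell in 7 of 23 cases (11 lower and 2 higher adjusted over the list alone), with Fabp7 at -1.91 ± 0.30 (camera adjusted p = 3.5e-05; adjusted p = 0.280 with an estimated correlation), and in 1 without D18N replicate 2. Named by size of change were the keratin gene Krt5 (651-fold higher, 116 to 25746), Tceal7 (377-fold, 104 to 3116), Igfn1 (367-fold, 65.4 to 14540) and Chrng (8.27 ± 0.63), and, lower, Marco (-4.21 ± 0.76), Ptgds (-4.03 ± 0.45) and Gjb2 (-3.68 ± 0.58). Of all genes 1155 passed, 671 higher and 484 lower (468 and 293 by at least 2-fold; 27.7% did not overlap, against 10% by chance). The count was 406, 445 and 769 without D18N replicate 2, Trex1-/- replicate 3 and D18N replicate 3, 1917 without Trex1-/- replicate 1, 2035 with DESeq2 and 417 with only both groups in the fit, and the length and GC offset gave 712 higher and 825 lower. Of the genes named by rule 29 of 57 kept their call whichever library was left out.

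Against Trex1-/-, p212fs had p53 targets higher, 14 of 29, and Sesn2 lower, also adjusted over the list alone (median 0.55, camera adjusted p = 4.3e-07; adjusted p = 0.146 with an estimated correlation), with Pmaip1 at 3.12 ± 0.23 and Perp at 4.01 ± 0.34. Matrix genes fell in 21 of 44 cases (23 adjusted over the list alone, median -0.72, adjusted p = 5.0e-08; adjusted p = 0.146 with an estimated correlation), with Col6a3 at -3.02 ± 0.22 and Col15a1 at -4.04 ± 0.29. Lysosomal genes rose in 21 of 36 cases and Npc1, like Sesn2 named after its value was seen, fell (23 and 1 adjusted over the list alone; camera adjusted p = 3.4e-07; adjusted p = 0.668 with an estimated correlation), with the protease genes Ctsd at 1.46 ± 0.18 and Ctsb at 1.01 ± 0.14. Interferon-stimulated genes fell in 13 of 55 cases (11 adjusted over the list alone, median -1.11), with the RNA sensor kinase gene Eif2ak2 at -1.67 ± 0.26, Slfn5 at -1.99 ± 0.39 and Ifi27l2a at -4.31 ± 0.73. For them camera gave adjusted p = 5.5e-04, and adjusted p = 0.977 with an estimated correlation. Without Trex1-/- replicate 2 the call ended, and 2 fell without p212fs replicate 1. Sprr2b (5.00 ± 0.82), Sncg (4.80 ± 0.24), the membrane protease gene St14 (6.33 ± 1.39 against 0.258 ± 0.187 CPM) and the clustered histone gene H4c8 (3.84 ± 0.55), uncertain like Sprr2b because of its copies, rose. Oas3 (-5.02 ± 1.26), Cldn11 (-4.92 ± 1.12), Hsd3b1 (-4.81 ± 1.05), Aqp4 (-4.46 ± 0.86) and Hif3a (-4.32 ± 1.01) fell, and each lost its call without a p212fs library. In all 5523 genes passed, 2611 higher and 2912 lower (850 and 1538 by at least 2-fold; 60.3% did not overlap, against 20% by chance), 1622 and 1777 without p212fs replicates 1 and 2, and 2552 higher and 1875 lower with the length and GC offset; 42 of 75 genes named by rule kept their call whichever library was left out.

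Against D18N, p212fs had all 25 muscle genes lower, also adjusted over the list alone (median -5.27, or -5.19 at bounds; camera adjusted p = 1.2e-29; adjusted p = 0.0877 with an estimated correlation), with Neb at -6.38 ± 0.46 and the embryonic myosin gene Myh3 at -7.24 ± 0.60. Targets of p53 rose in 20 of 29 cases and fell in 4, Ddit4, Trp53cor1, Sesn2 and Rrm2b, also adjusted over the list alone (median 1.15, adjusted p = 1.2e-11; adjusted p = 0.0876 with an estimated correlation), with Psrc1 at 2.27 ± 0.14 and the death receptor gene Tnfrsf10b at 63.5 ± 8.80 against 22.4 ± 2.09 CPM. Matrix genes fell in 22 of 44 cases and rose in 3, Timp2, Fbln5 and Fmod (22 and 4 adjusted over the list alone, median -0.81, adjusted p = 2.5e-08; adjusted p = 0.0877 with an estimated correlation). Col6a3 stood at -3.94 ± 0.23 and Col1a2 at -1.95 ± 0.17. Macrophage markers rose in 14 of 20 cases, also adjusted over the list alone, with Lyz2 at 2.96 ± 0.32 (camera adjusted p = 7.5e-09; adjusted p = 0.338 with an estimated correlation), and in 7 without p212fs replicate 2. Lysosomal genes rose in 19 of 36 cases and fell in 2, Npc1 and Ctsk, also adjusted over the list alone, with Gusb at 1.17 ± 0.12 (camera adjusted p = 8.7e-06; adjusted p = 0.622 with an estimated correlation). Cell cycle genes rose in 9 of 40 cases (7 adjusted over the list alone, camera adjusted p = 4.2e-04; adjusted p = 0.900 with an estimated correlation), with Ccne1 at 2.07 ± 0.29, and in 2 without p212fs replicate 2. Cartilage and bone markers rose in 6 of 17 cases and fell in 1, also adjusted over the list alone, with Col2a1 at 7.95 ± 0.81 and Runx2 at -0.94 ± 0.15. For this list camera gave adjusted p = 0.0056, and adjusted p = 0.622 with an estimated correlation. The p53 and lysosomal genes that fell and the matrix genes that rose were named after their values were seen. Of all 16990 genes tested 3153 were higher in p212fs than in D18N, a share close to 9 of 40 cell cycle genes.

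Other genes named by size of change between p212fs and D18N were Sprr2b (at least 108-fold higher), Elobl (6.76 ± 0.74), Mcpt8 (5.30 ± 0.98) and the neurotrophin Ntf3 (4.63 ± 0.80). Myh4 was at least 145-fold and Tmem182 at least 74.5-fold lower, Myh1 819-fold (147 to 32394) and Mylk4 478-fold (85.4 to 18896) lower, and Myh8 fell by 9.50 ± 0.73 on the log2 scale; the myosin genes lie in a cluster of similar copies, so reads may be split between them. Of interferon-stimulated genes 4 of 55 fell (3 adjusted over the list alone; camera adjusted p = 0.392), Ifi27l2a (-4.51 ± 0.74), Slfn5 (-2.10 ± 0.39), Eif2ak2 and Oas2, the last named after its value was seen, and of 18 MHC class I genes H2-T24 did (-3.57 ± 0.51). In all 6571 genes passed, 3153 higher and 3418 lower (1077 and 2026 by at least 2-fold; 69.8% did not overlap, against 20% by chance), 2674 and 3231 without p212fs replicates 1 and 2, and 3830 higher and 2397 lower with the length and GC offset. Of 78 genes named by rule that passed, 61 kept their call whichever library was left out.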

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

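The tests of myogenic cells and of fewer macrophages, with the genes used in them, and those of embryo sex for the interferon-stimulated genes were chosen after the results were seen, as was the offset for gene length and GC content.

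In D18N, markers of skeletal muscle lay far above WT and markers of macrophages below it. Embryo sex is argued against for the muscle genes, since the D18N library of female pattern, replicate 1, exceeded the highest WT library by 6.28 in the list's mean log2 CPM, and the male-pattern libraries of Trex1-/- and p212fs had means of -0.25 to 0.50. Myogenic cells in the D18N cultures are a candidate explanation. Of 18 tested muscle genes outside the list 94.4% passed as higher, against 12.1% of all genes. Genes near 0 in WT entered this test only through libraries where they were high. The filter may thus have set part of that share, and 12.1% is no like background for such genes. Myh3 had 557, 224 and 239 CPM and Acta1 329, 152 and 128 CPM in D18N replicates 1, 2 and 3. Of the 25 list genes 11 had at least 1 CPM in WT, and Des is also on the myofibroblast list. Fewer macrophages in the D18N cultures may account for the other part. Of 20 tested macrophage genes outside the list 90% passed as lower, against 13.2% of all genes, while all 20 list genes had at least 1 CPM in WT. A changed expression of these genes within the same cells was not told apart from a changed make-up of the cultures, and neither the genotype nor differences between embryos and dissections were tested as its source.

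Interferon-stimulated genes were far higher in Trex1-/- replicate 2 than in replicates 1 and 3. The antiviral gene Ifit1 had 731 CPM there against 135 and 182, and 82.8, 45.5 and 43.5 in WT. Embryo sex cannot be told apart from the library, since replicate 2 was the only Trex1-/- library of female pattern; its list mean lay 1.65 log2 CPM above the highest female-pattern library of the other genotypes, which does not bear on sex within Trex1-/-. A wrong genotype label cannot be told apart from a true one: outside the immune lists, replicate 2 correlated with the other Trex1-/- libraries by only 0.000374 more than with WT (r = 0.970 for both), and WT replicate 2 correlated with Trex1-/- at 0.985 and with the other WT at 0.983, although the macrophage list mean of 1.98 log2 CPM goes with the label (2.30 and 2.90 in the other Trex1-/- and 3.41 to 4.15 in WT), as does Lyz2 at 142 CPM (153 and 240 against 645 to 754). Macrophage content need not follow the genotype and Trex1 was at 0 counts throughout, so the label stays open, as does a response of that culture to the loss of Trex1, on which no test here bears.

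Long genes lay lower in p212fs than in WT. The trend is argued against as the whole cause of the changes in p53 targets and extracellular matrix genes. Their medians were 0.78 and -0.50 with the length and GC offset, against 0.81 and -0.57 without it. Both kept their camera call at the preset correlation, while the MHC class I list and that of cartilage and bone markers lost theirs. Camera ran on log2 CPM with the offset and on counts without it, so the lost calls are not shown to come from length or GC content. Without the offset the matrix list had a camera adjusted p of 0.0693 with an estimated correlation. Embryo sex as the source of the trend cannot be told apart from genotype. The slope per doubling of gene length between p212fs and WT was -0.0517 from the fitted log2 fold changes and -0.0803 from mean log2 CPM, and on the latter scale it was 0.0379 between male- and female-pattern libraries of Trex1-/- and -0.00623 in D18N, but WT replicate 1 differed from the other WT libraries, of the same sex pattern, by -0.114. Differences in RNA quality between libraries, for which the labels hold no measure, and the frameshift itself stay open and untested.

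Table lines without a gene name, which entered no comparison, took 0.129% of the reads of Trex1-/- replicate 2, 0.0966% of those of D18N replicate 2, and 0.113% of those of both p212fs libraries, above the highest WT library at 0.0957%.

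The 6 libraries of 3 against 3 comparisons make 10 splits, which are too few for a share under 0.05. By edgeR, the real split called 4303 genes between D18N and WT and 1155 between D18N and Trex1-/-, where the highest other split called 0, so that 1 of 10 splits reached the real count in each. Every other split mixed libraries of both genotypes in each part, so that differences between genotypes entered the spread. Few or no calls were thus to be foreseen there, and the 0 lends no support to the grouping. Between Trex1-/- and WT the real split called 0, as did the highest other, so that 10 of 10 splits reach it by definition and the count says nothing about chance.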

How the results depend on the processing

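The length and GC offset, and the sex term for gene lists, were chosen after seeing the data. Of the comparisons between settings for named genes and gene lists, 9098 kept the side of the threshold, 748 lost the call, 47 gained one and 4 turned direction. For named genes a turn of direction was counted only where at least 1 of both settings gave a call. Lists entered this tally only where the main setting called them. Gains of a call and turns of direction in other lists are therefore not in it. Of the comparisons for counts, numbers of lists and shared changes, 234 stayed and 72 moved. DESeq2 size factors shifted the median of all genes by no more than -0.0125. Total counts of 16073955 to 21765536 limit what can be said of genes with few counts, such as 6 of the muscle genes in WT, whose folds are given with counting intervals or as bounds. Leaving out 1 of the 2 p212fs libraries assumed that the lone library varied like the other groups. Except where stated, the cause was not tested.

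Counts of genes past the threshold moved by over 1.5 times as follows. Between Trex1-/- and WT, where edgeR called 0, no filter gave 261, DESeq2 846, limma-voom 1 and the sex term 380. The sex term gave 2379 in place of 4303 between D18N and WT and 1331 in place of 2902 between p212fs and WT. Between D18N and Trex1-/-, 1155 became 2035 with DESeq2 and 417 with only both groups in the fit, which leaves fewer libraries to estimate the spread. With 1 library left out, the counts ran from 0 to 2269 for Trex1-/- against WT (highest without WT replicate 2), 1662 to 5350 for D18N against WT (lowest without D18N replicate 2, highest without WT replicate 2) and 494 to 3947 for p212fs against WT (without p212fs replicate 1, without WT replicate 1). They ran from 406 to 1917 for D18N against Trex1-/-, 1622 to 6254 for p212fs against Trex1-/- and 2674 to 7185 for p212fs against D18N. The length and GC offset gave 0, 4586, 2789, 1537, 4427 and 6227 in the same order of comparisons.

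Of 26 lists, camera called 9, 9, 12, 14, 4 and 7 in that order, and 0, 2, 1, 1, 0 and 0 with an estimated correlation, a wider allowance for genes that vary together. Fry, which asks another question, called 1, 3, 4 and 7 in the first 4 comparisons. The sex term gave 14 for D18N against WT. With 1 library left out the numbers ran from 6 to 10, 8 to 13, 9 to 13, 10 to 15, 4 to 9 and 7 to 11.

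Correlations of log2 fold changes rose to 0.656 for Trex1-/- and D18N and 0.268 for D18N and p212fs among genes with a mean of at least 10 CPM, where 338 genes were called in the same direction in D18N and p212fs in place of 594, over fewer genes. With 1 library left out they ran from 0.447 to 0.614 for Trex1-/- and D18N, 0.190 to 0.309 for Trex1-/- and p212fs and 0.149 to 0.264 for D18N and p212fs, and the genes called in the same direction from 0 to 1786, 0 to 131 and 111 to 830.

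Among lists called in the main setting, all 4 that turned direction did so without Trex1-/- replicate 2. Against WT, inflammatory genes in Trex1-/- had a camera adjusted p of 0.210 then (0.0042 with all libraries, 7.8e-10 to 0.210 with 1 library left out, 1.8e-20 to 0.957 over all alternatives). Between D18N and Trex1-/-, interferon-stimulated genes had 0.771 (1.1e-04, 1.8e-12 to 0.771 and 1.8e-12 to 0.786), inflammatory genes 0.0866 (0.0083, 1.2e-05 to 0.0944 and 1.2e-05 to 0.786) and MHC class I genes 0.482 (0.0445, 4.9e-04 to 0.482 and 4.9e-04 to 0.786).

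With the replicate number as a replicate block, 0, 3801, 1966, 881, 4701 and 5930 genes passed, and camera called 8 lists between p212fs and Trex1-/- in place of 4. The numbers were not taken to pair libraries: the deviations of libraries that share a number correlated at -0.209 to 0.140, over 0.1 in 2 of 15 pairs, and 5 of 11 libraries correlated best with their own number, a hint from the data and not from the design.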

Other observations

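Single genes of other lists that mark cell identity also passed between D18N and WT, although none of the lists in this paragraph passed by camera. The epithelial and adipocyte lists did with the length and GC offset, added after seeing the data, where camera ran on log2 CPM. Of 13 epithelial markers 4 rose, Krt5, a basal keratin (190-fold, 64.8 to 925), the desmosomal gene Dsp (2.88 ± 0.47), Trp63 and Cldn4, and Krt7 (-2.11 ± 0.40) and Krt19 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.0669). Adipocyte markers rose in 3 of 13 cases, also adjusted over the list alone (camera adjusted p = 0.0900), with the lipid droplet gene Plin4 at 2.35 ± 0.65, the gluconeogenic enzyme Pck1 at 3.04 ± 0.93 and lipoprotein lipase, Lpl, at 1.37 ± 0.41. Pck1 had few counts, with 0.624 to 0.739 CPM in D18N and 0.054 to 0.115 in WT. The adipocyte list means overlapped, at 3.79, 2.35 and 2.80 log2 CPM in D18N and 2.95, 1.20 and 1.28 in WT. Positional factors moved both ways, 6 of 42 higher and 10 lower (6 and 11 adjusted over the list alone; camera adjusted p = 0.112), with Pax1 at -2.40 ± 0.39, Irx3 at -1.13 ± 0.19 and Barx1 at -2.95 ± 0.58. Of 14 endothelial markers Pecam1 (2.19 ± 0.60) and Kdr rose and Flt1 (-1.30 ± 0.27) and Erg (-1.96 ± 0.57) fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.472). Pecam1 had few counts, with 0.624 to 1.19 CPM in D18N and 0.115 to 0.245 in WT. Imprinted genes had the noncoding RNAs Meg3 (1.15 ± 0.22), Mirg (0.80 ± 0.22) and Rian (0.76 ± 0.23) of a single locus higher and Dlk1 of the same locus lower, of 21 and also adjusted over the list alone (camera adjusted p = 0.373). Trp63, Cldn4, Krt19, Kdr and Dlk1 were named here after their values were seen.

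Of 21 senescence genes in D18N, 5 fell, Cdkn2a (-1.49 ± 0.25), Lmnb1 (-1.06 ± 0.20), Cdkn2c (-1.11 ± 0.23), Cdkn2b and Trp53, and Rb1, Glb1 and Cdkn1b rose, also adjusted over the list alone (camera adjusted p = 0.187). Sensing genes had 6 of 26 lower and 5 higher, also adjusted over the list alone (camera adjusted p = 0.956). Those lower included Rnaseh2c (-1.04 ± 0.23) and Rnaseh2b (-0.84 ± 0.19), subunits of ribonuclease H2, and Slc19a1 (-0.78 ± 0.18), and those higher were Zdhhc1, Enpp1, Ifi203, Ikbke and Trim56. Of 29 glycosylation genes Alg8 (-1.23 ± 0.19), Dad1 (-0.79 ± 0.19) and Alg3 (-0.81 ± 0.22) fell and Alg2 and Alg11 rose (3 lower and 0 higher adjusted over the list alone; camera adjusted p = 0.373). The cholesterol list, of 24 genes, had a camera adjusted p of 0.472, with Mvk (-0.77 ± 0.17) and Ebp (-0.75 ± 0.18) among the genes that passed. Lysosomal genes had 5 of 36 higher, Npc1 (0.85 ± 0.16), Lamp2 (0.72 ± 0.16), Glb1, Ctsl and Lipa, and Gusb (-0.54 ± 0.11) and Ctsd lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.550). Of 31 inflammatory genes Tnfaip2 rose (0.94 ± 0.27) and Cx3cl1 fell (-1.19 ± 0.24), with 0 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.994). Cdkn2b, Trp53, Rb1, Cdkn1b, the sensing genes that were higher, Alg2, Alg11, Glb1, Ctsl, Lipa and Ctsd were named after their values were seen. Over all genes 12.1% were higher and 13.2% lower in D18N than in WT, against 13.9% and 5.56% of lysosomal genes.

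In p212fs, Dlk1, an imprinted gene of preadipocytes, fell from 684 ± 10.0 to 72.2 ± 6.76 CPM (-3.24 ± 0.63), while the imprinted genes Snrpn (1.11 ± 0.21) and Nnat (1.34 ± 0.28) rose (3 higher and 3 lower of 21 adjusted over the list alone; camera adjusted p = 0.626). Positional factors had Msx2 (2.24 ± 0.36), Pax9, Lhx9 and Alx1 higher of 42 and 6 lower, among them Osr2 (-2.80 ± 0.56) and Alx4 (-1.37 ± 0.28), with 5 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.649). Of 13 epithelial markers Dsp (2.14 ± 0.50), Cldn3 (3.03 ± 0.80), Elf3 (2.61 ± 0.71) and Cldn4 rose and Krt7 and Krt19 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.649), and none passed with the sex term; the list's median of -0.10 and mean of 0.24 differed in sign. Endothelial markers had Eng higher (0.98 ± 0.24) and Flt1 (-2.99 ± 0.34) and Cdh5 (-2.13 ± 0.62) lower of 14 (2 and 2 adjusted over the list alone; camera adjusted p = 0.977). The adipocyte genes Cebpa (-1.30 ± 0.31) and Lpl (-1.86 ± 0.49) fell, 2 of 13, also adjusted over the list alone (camera adjusted p = 0.367). Pax9, Lhx9, Alx1, Cldn4, Krt7 and Krt19 were named here after their values were seen.

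Of 21 senescence genes Cdkn1a, Glb1 (0.93 ± 0.17) and Rb1 rose in p212fs, and Cdkn2c (-1.23 ± 0.27), Lmnb1 and Igfbp3 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.626). Sensing genes had Tmem203 (0.90 ± 0.26) and Ikbke (0.96 ± 0.30) higher and Slc19a1 (-0.67 ± 0.20) lower of 26, and 0 adjusted over the list alone (camera adjusted p = 0.583). Of 29 glycosylation genes Ost4 rose (0.85 ± 0.15) and Man2a1 fell (-1.41 ± 0.28), also adjusted over the list alone (camera adjusted p = 0.583). Hypoxia genes had Gapdh higher (3.14 ± 0.47) and Ndrg1 (-0.88 ± 0.18) and Ero1a (-0.67 ± 0.17) lower of 28, also adjusted over the list alone (camera adjusted p = 0.649); Gapdh stood at 218 ± 124 against 24.6 ± 1.55 CPM, and its many pseudogene copies make this count uncertain. Of 4 erythroid markers Epor rose (1.93 ± 0.50), also adjusted over the list alone (camera adjusted p = 0.260). Of 5 sex-linked genes 0 passed in p212fs and Uty alone in D18N, and 4 in each adjusted over the list alone (camera adjusted p = 0.0974 and 0.304). Rb1, Lmnb1, Igfbp3 and Uty were named after their values were seen.

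Several of these lists separated D18N from Trex1-/- by camera at the preset correlation but not with an estimated one. Hypoxia genes had 5 of 28 higher, Ddit4 (0.97 ± 0.15), Ero1a (0.84 ± 0.15), Vegfa (1.07 ± 0.22), Aldoc and Ndrg1, and 6 adjusted over the list alone (camera adjusted p = 3.5e-05; adjusted p = 0.587 with an estimated correlation). Positional factors had 4 higher and 12 lower (7 and 16 adjusted over the list alone), with Pax1 at -3.15 ± 0.40 and Pax9 at -1.88 ± 0.26 (camera adjusted p = 0.0011; adjusted p = 0.301 with an estimated correlation). Epithelial markers had Krt5, Dsp (2.10 ± 0.44), Krt14 (2.78 ± 0.71) and Epcam higher, and 5 adjusted over the list alone (camera adjusted p = 0.0011; adjusted p = 0.311 with an estimated correlation). Of p53 targets 7 fell, with Aen at -0.93 ± 0.15 and Epha2 at -1.26 ± 0.23, and Ddit4, Pmaip1 and Trp53cor1 rose (12 and 3 adjusted over the list alone; camera adjusted p = 9.4e-04; adjusted p = 0.282 with an estimated correlation). Among senescence genes Cdkn2a (-1.31 ± 0.25), Cdkn2b (-0.65 ± 0.15), Lmnb1 (-0.79 ± 0.20) and Mmp13 fell (5 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0209; adjusted p = 0.285 with an estimated correlation). The adipocyte gene Lpl rose (1.88 ± 0.42), with 4 higher adjusted over the list alone (camera adjusted p = 0.0024; adjusted p = 0.456 with an estimated correlation). Inflammatory genes had Cx3cl1 lower (-1.63 ± 0.24), also adjusted over the list alone, and MHC class I genes Erap1 lower (-0.80 ± 0.21), with 0 adjusted over the list alone (camera adjusted p = 0.0083 and 0.0445; adjusted p = 0.786 with an estimated correlation for both), and both lists turned direction without Trex1-/- replicate 2. The calls of the senescence, inflammatory and MHC class I lists ended with the length and GC offset. Aldoc, Ndrg1, Epcam, Pmaip1, Trp53cor1 and Mmp13 were named after their values were seen.

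In Trex1-/- against WT no member of the sensing, senescence, positional, epithelial, endothelial, adipocyte, imprinted, glycosylation, cholesterol, erythroid, sex-linked, matrix, Hox, lysosome, hypoxia, neuronal or muscle lists passed over all genes by edgeR. Adjusted over the list alone, 6 sensing genes were higher and 3 lower, 2 positional factors and 4 sex-linked genes higher, and 1 glycosylation and 1 Hox gene lower. The camera adjusted p of these lists ran from 0.101 for the sex-linked genes to 0.971 for the cholesterol and erythroid lists.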
